A study of Mus musculus with 20 samples.

How the data were processed

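RNA was sequenced from 20 tumours grown from CT26 cells, a colon carcinoma line of BALB/c mice. Per the labels, 10 tumours came from cells carrying a POLE mutant and 10 from cells carrying the empty vector, and 5 of each received PBS and 5 an antibody against PD-1. POLE is the catalytic subunit of the replicative DNA polymerase epsilon. The series title names CHEK2, a DNA damage checkpoint kinase, while every sample label and the design text name POLE, so the mutant group is called mutant here and both genes are reported. The design text gives 5 mice per group. Replicate numbers were given in deposition order and only name a tumour.

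The deposited files hold 1 value per gene and library, taken as FPKM (fragments scaled by transcript length and by library size). The header names no unit. FPKM was read from Cuffnorm in the submitters' processing notes and from values that are never negative, are not whole and sum to different totals. Those notes also name FastQC, STAR 2.5, a differential expression package and the mm10 build, with no role or order. The annotation, the handling of reads that match several genes, strandedness and any scaling between libraries are not given in the sources used here. The files list 55335 genes by Ensembl identifier, of which 55154 were matched to symbols in the GENCODE vM21 annotation of mm10. Coordinates come from that annotation. In 1 file, 10 extra columns were empty.

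The depth of each library is unknown. Low values were searched for a step that would turn them into whole reads, and at the best step between 19.0% and 24.7% of them were whole within 5%, so no read numbers were recovered and no counting interval is given. Per-library totals of FPKM ran from 328740 to 566913. No pair of libraries held identical values, and the highest Spearman correlation between libraries was 0.929. The design fixed in advance named a test for read counts and, for files of normalized values, limma. The second applied.

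Values were analysed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 5 libraries were kept, which left 13982. limma 3.58.1 in R 4.3.3 with an intensity trend was fitted to all 20 libraries with 4 group means, so that all groups share 1 estimate of the spread, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The fit has a term for the style of the animal identifier in the sample title, which is M and a number in 11 libraries and a number alone in 9. The labels do not say what the style marks. It splits 3 to 2 in each group except mutant anti-PD-1, where it splits 2 to 3. The term itself passed the threshold for 6 genes, and 2982 genes had an unadjusted p under 0.05 for it. The 7 contrasts were anti-PD-1 against PBS in each tumour type, mutant against vector under each treatment, the difference of the responses (interaction), and the mean genotype and mean treatment differences.

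Before the data were examined, 29 gene lists holding 509 genes were fixed from textbook knowledge of immune cells, interferon responses, antigen presentation, DNA damage, proliferation, stress, stroma and neighbouring tissues. The files held 505 of these genes, and 419 were tested. Lists with at least 5 tested genes were tested, 27 in all. The keratinocyte and mammary lists had 2 and 1 tested genes and were left out. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 27 lists of a contrast. With a correlation estimated from the data, camera called 0 lists in each of the 7 contrasts. limma's fry, a rotation test of whether a list's genes move on balance 1 way, was run beside it. A list's score in a tumour is the mean log2(FPKM + 1) of its tested genes. Scores were compared by exact two-sided permutation tests of 5 against 5 tumours (252 arrangements, smallest possible p 0.00794), adjusted over the 27 lists, in Python 3.11.15 with numpy 2.4.6. A list at that smallest p passes after adjustment only if several other lists are also low. Failing this test is therefore weak evidence of no difference.

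Genes named in each comparison were chosen by a rule fixed before the data were examined. They are a panel of 20 genes; the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2(FPKM + 1) of at least 1; and up to 4 members of a described list with the smallest p. Predicted genes and antigen-receptor segments were left out of the second group. Where no gene passed, the 5 with the smallest p in each direction are given as not past the threshold. Foxp3 of the panel fell below the filter and has levels but no test. Other genes of the panel are not reported here. Genes of families with near-identical members, such as the granzyme cluster, Tgtp1 and Tgtp2, the H2-Q genes and the Zfp cluster of chromosome 4, can share reads, so their single values are uncertain. The mice and cells are BALB/c and mm10 is C57BL/6, so levels of polymorphic H2 genes can be biased, equally in all groups.

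The fit was tested on simulated data with the real gene means and spreads and 50 genes changed at each fold size. For 2-fold changes it recovered 42% for the vector response, 60% for the mutant response, 54% for mutant against vector under PBS and 56% under anti-PD-1. For 4-fold changes it recovered 78%, 94%, 92% and 84%. False calls numbered 5, 3, 7 and 12. Simulated values carry no correlation between genes. Each contrast used the same spreads and newly drawn genes, so these shares do not rank the contrasts by power.

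Alternatives fixed in advance were median centring, limma without the trend, no filter or a stricter one, a pseudocount of 0.1, no style term, only the compared groups, each identifier style alone, a 2-fold minimum, estimated correlation, fry, other list scores, permutation within identifier style, and leaving out each library. Chosen after seeing the data were a fit without the 3 libraries least correlated with the rest, a fit with the skeletal muscle score as a term, and sample quality weights. Tests that need read counts were not run.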

Results

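Gene expression was measured by RNA sequencing in 20 tumours grown from CT26 mouse colon carcinoma cells. The 4 groups of 5 tumours were vector with PBS, vector with anti-PD-1, mutant with PBS and mutant with anti-PD-1. PD-1 is a receptor that restrains activated T cells, and an antibody that blocks it can release them. Values are FPKM as deposited, tested as log2(FPKM + 1) with limma, and a log2 fold change is given with its SE or a mean with its SD, each with n = 5 per group. The depth of the libraries is unknown. Between 11182 and 13769 genes reached 1 FPKM in a library, and mitochondrial genes took 2.85% to 11.1% of the total.

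The first principal component held 43.8% of the variance and set mutant anti-PD-1 tumours apart. The second held 25.4% and set 1 library apart, vector anti-PD-1 replicate 1, at 118. That library had a total of 566913 FPKM against a median of 355875, took 8.40% of it from small RNA genes, and correlated with the other libraries at a mean Spearman value of 0.873. Mutant anti-PD-1 replicates 1 and 2 had values of 0.874 and 0.889, and the other 17 libraries lay between 0.905 and 0.913. These 3 low libraries all carry M-style identifiers, and replicates 1 and 2 are the only M-style ones of mutant anti-PD-1. The fit without these 3 libraries and the split by identifier style are therefore not separate checks wherever mutant anti-PD-1 is compared. Skeletal muscle genes, which mark tissue beside a tumour, varied within groups, with a score of 0.65 ± 0.19 in vector PBS, 2.13 ± 1.75 in vector anti-PD-1, 2.07 ± 2.21 in mutant PBS and 3.90 ± 1.34 in mutant anti-PD-1 tumours (SD, n = 5).

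**Figure D1:**
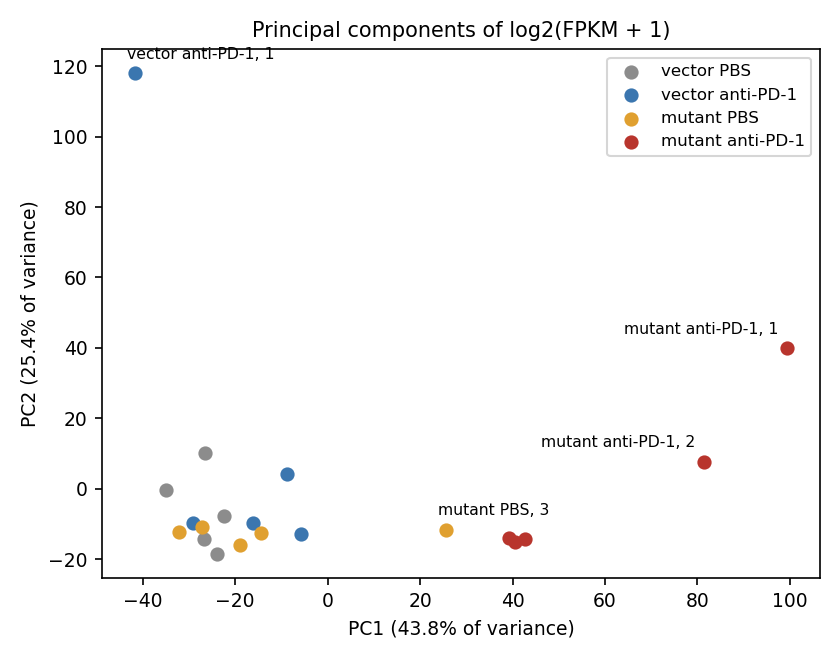
Each point is 1 tumour placed by its first and second principal components of log2(FPKM + 1), coloured by group. The first component holds 43.8% of the variance, and vector anti-PD-1 replicate 1 lies at 118 on the second.

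Pole (ENSMUSG00000007080, chromosome 5, 110286306 to 110337474 of mm10) encodes the catalytic subunit of DNA polymerase epsilon and is the gene the sample labels name. It measured 8.62 ± 1.64 FPKM in vector PBS, 7.51 ± 2.28 in vector anti-PD-1, 5.22 ± 0.872 in mutant PBS and 3.94 ± 1.69 in mutant anti-PD-1 tumours (SD, n = 5). Pole was lower in mutant than in vector tumours averaged over the treatments, by a log2 fold change of -0.78 ± 0.129 (SE, adjusted p = 0.0003), and lower under anti-PD-1 alone at -0.93 (adjusted p = 0.000963). Under PBS the change of -0.62 did not pass (adjusted p = 0.120), although the mutant tumours at 4.14 to 6.35 FPKM lay below the vector tumours at 6.45 to 10.4. Chek2 (ENSMUSG00000029521, chromosome 5, 110839979 to 110874145), a checkpoint kinase gene and the one in the series title, measured 6.43 ± 1.23, 5.01 ± 1.34, 6.44 ± 1.34 and 5.03 ± 1.32 FPKM in the same order. Chek2 did not differ past the threshold between mutant and vector tumours, with log2 fold changes of -0.001 under PBS (adjusted p = 0.998) and -0.07 under anti-PD-1 (adjusted p = 0.715). Compared with PBS, anti-PD-1 tumours had lower Chek2 averaged over the tumour types (adjusted p = 0.0154, past the threshold in 22 of 24 alternatives). In mutant tumours alone Chek2 (adjusted p = 0.034) and Pole (adjusted p = 0.0399) were lower, past the threshold in 7 and 5 of 14 alternatives. Expression of an introduced human sequence was not analysed here.

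**Figure D2:**
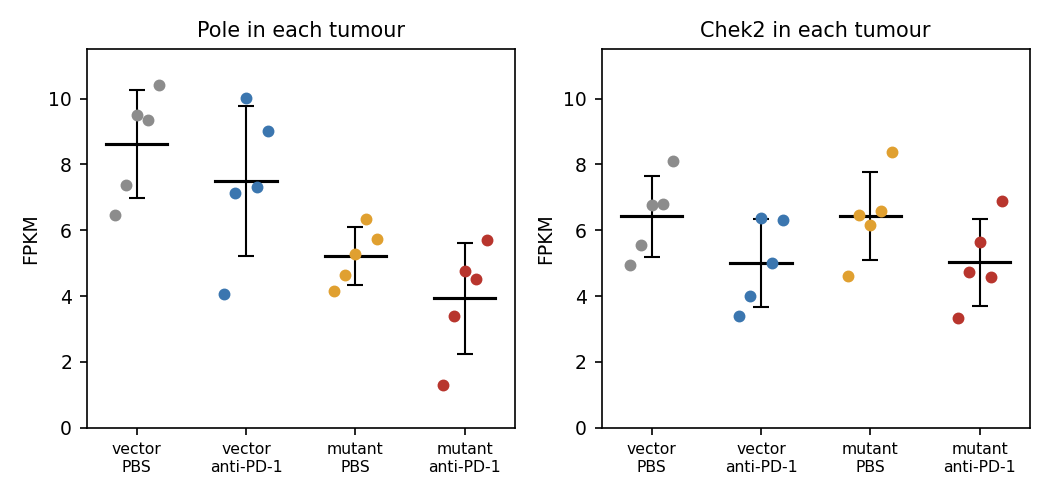
Each point is the FPKM of Pole or Chek2 in 1 tumour, the line is the group mean and the bars are the SD of 5 tumours. Mean Pole is 8.62 in vector PBS and 3.94 in mutant anti-PD-1 tumours, and mean Chek2 is 6.43 and 5.03.

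Mutant tumours were compared with vector tumours under PBS, which addresses how these tumours and their immune surroundings differed without antibody. The labels name no separate clones. The mutant therefore cannot be told apart from other differences between the mutant and vector cells, here and in every comparison of the tumour types. Some genes that interferon-gamma induces were higher in the mutant tumours. Among them were the T cell attractant Cxcl9, the guanylate-binding protein Gbp2b, and some MHC class II genes, which present antigen to CD4 T cells. Cxcl9 (ENSMUSG00000029417, chromosome 5, 92321347 to 92328079) rose from 2.09 ± 1.81 to 39.5 ± 41.8 FPKM (SD, n = 5), a log2 fold change of 3.29 ± 0.643 (SE, adjusted p = 0.0125). H2-Aa (ENSMUSG00000036594, chromosome 17, 34282744 to 34287823) rose from 2.87 ± 1.35 to 44.1 ± 66.8 FPKM (log2 fold change 2.56, adjusted p = 0.0347). Much of both mutant means came from mutant PBS replicate 3, at 112 FPKM of Cxcl9 and 163 of H2-Aa, against 6.58 to 35.4 and 5.73 to 28.8 in the other 4. Ubd rose by a log2 fold change of 2.93 (adjusted p = 0.0019), Tgtp1 by 2.90 (adjusted p = 0.0119) and Cd74, the class II chaperone, by 2.66 (adjusted p = 0.0153). H2-Ea-ps, Gbp2b, H2-Eb1, H2-Ab1 and Tgtp2 were the other genes among the 10 largest rises.

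A cluster of granzyme genes fell. Granzymes are proteases of cytotoxic lymphocytes, and these members lie beside Gzmb. Gzmg went from 39.3 ± 38.2 to 0.302 ± 0.29 FPKM (log2 fold change -4.16, adjusted p = 0.02) and Gzmc from 41.0 ± 36.4 to 2.21 ± 1.9 FPKM (log2 fold change -3.40, adjusted p = 0.013), with Gzmf, Gzmd and Gzme also lower. Gzmb itself did not pass (log2 fold change -0.86, adjusted p = 0.699). C78283 went from 6.60 ± 1.10 FPKM to being listed at 0 in all 5 mutant PBS tumours (adjusted p = 1.29e-05). Oplah, Hmgb1-ps8, the lymphatic vessel gene Lyve1 and the deiodinase Dio2 complete the 10 largest falls. In all 203 genes differed, 74 higher and 129 lower, 84 of them at least 2-fold. The count was 83, 105 and 102 without vector PBS replicates 1, 2 and 3, and 129, 98 and 116 without mutant PBS replicates 1, 2 and 4. The calls for Cxcl9, Ubd, Tgtp1, C78283, Oplah, Hmgb1-ps8 and Dio2 held in all 14 alternative fits run for single genes. Of the 10 fits that left out 1 library, Gzmf held only without vector PBS replicate 4 or mutant PBS replicate 4 (adjusted p up to 0.0989), and H2-Aa only without mutant PBS replicate 1, 3 or 5 (adjusted p up to 0.0966). The calls for H2-Eb1 and H2-Ab1 were lost without vector PBS replicate 1, 2, 3 or 5 or mutant PBS replicate 2 or 4, and that for H2-Ea-ps in 5 of those 6 fits, all but that without vector PBS replicate 3. Gbp2b and Tgtp2 were lost without vector PBS replicate 2, 3, 4 or 5 or mutant PBS replicate 2, 3 or 4. Gzmd, Gzme and Gzmg were lost without vector PBS replicate 1 or 2 or mutant PBS replicate 1 or 2, and Gzme also without vector PBS replicate 5. Lyve1 was lost without vector PBS replicate 1, 3, 4 or 5 or mutant PBS replicate 1 or 2, Cd74 without vector PBS replicate 1 or 2, and Gzmc without vector PBS replicate 1. In these fits adjusted p reached 0.0836 at most, and the muscle term also ended the calls for the H2 genes, Gbp2b, Tgtp2, Gzmd, Gzme, Gzmf and Gzmg. Dropping the style term ended those for H2-Aa, Gzme and Gzmf.

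Of the gene lists, interferon-gamma response had 6 of 22 genes risen and 16 not past the threshold (17 risen adjusted over the list alone), with a median log2 fold change of 1.76 (camera adjusted p = 9.25e-22, adjusted p = 0.291 with an estimated correlation). MHC class II had 5 of 8 genes risen (8 adjusted over the list alone), with a median of 2.33 (camera adjusted p = 3.95e-12, adjusted p = 0.291 with an estimated correlation). Without mutant PBS replicate 3 the medians were 1.30 and 1.72, and among M-style libraries they were 1.73 and 2.73 against 1.84 and 1.60 among number-only libraries. The class II score was 3.65 ± 1.46 in mutant and 1.64 ± 0.28 in vector tumours with no overlap. Its exact permutation p was 0.00794, the smallest possible, and did not pass after adjustment (adjusted p = 0.107). No MHC class I gene passed over all genes and 6 of 20 rose adjusted over the list alone (median 0.52, camera adjusted p = 1.52e-08, adjusted p = 0.398 with an estimated correlation), with a median of 0.29 without mutant PBS replicate 3. No p53 target passed (median 0.28, camera adjusted p = 0.000617, adjusted p = 0.46 with an estimated correlation), nor did an unfolded protein response gene (median 0.40, camera adjusted p = 0.000191, adjusted p = 0.291 with an estimated correlation). The p53 list holds genes such as Cdkn1a that are switched on by DNA damage. Its score was 3.75 ± 0.15 against 3.49 ± 0.09 with no overlap (exact permutation p = 0.00794, adjusted p = 0.107). The T cell list was higher by a median of 0.39 with 0 of 17 genes past the threshold and 2 adjusted over the list alone, a median of 0.11 without mutant PBS replicate 3 (adjusted p = 0.641 with an estimated correlation for the full set). The checkpoint, adipocyte, immediate early and skeletal muscle lists were also higher by camera (adjusted p = 0.641, 0.641, 0.869 and 0.673 with an estimated correlation) and the cell cycle list was lower (median -0.27, camera adjusted p = 0.00146, adjusted p = 0.869 with an estimated correlation). Without mutant PBS replicate 3 the checkpoint list (median 0.01) and the adipocyte list (0.33) were no longer called. The immediate early list (camera adjusted p = 0.0479) lost its call without vector PBS replicate 1, 2 or 3, without mutant PBS replicate 1, and without the 3 libraries least correlated with the rest (adjusted p = 0.064). None of these 5 lists, cell cycle included (median -0.15, adjusted p = 0.781), was called among number-only libraries. The CD8 and cytotoxic list was not called (adjusted p = 0.831), and its median of 0.23 and mean of -0.53 differed in sign. In total camera called 11 lists here, and fry and the exact score test called 0. The fully separated lists were too few to pass the exact test after adjustment. Each identifier style alone gave 12 genes (M-style) and 140 genes (number-only).

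Anti-PD-1 was compared with PBS in vector tumours, which addresses the antibody's effect without the mutant. Class II, interferon-gamma and skeletal muscle genes were higher as lists by camera at its preset correlation. No list was called with an estimated correlation, and no gene passed the threshold. Cxcl9 measured 2.09 ± 1.81 FPKM with PBS and 22 ± 20.7 with anti-PD-1 (SD, n = 5), a log2 fold change of 2.61 ± 0.643 (SE, adjusted p = 0.724), and Cd74 measured 11.4 ± 3.2 and 64.7 ± 58.8 (log2 fold change 2.11, adjusted p = 0.724). Ubd, Snord100 and Psmb9 were the other genes among the 5 smallest p-values on the higher side. Spcs2, Zfp808, Tpcn1, Eri2 and Pot1b had the smallest on the lower side, with Spcs2 at 25.6 ± 1.76 and 11.2 ± 4.75 FPKM, and none of them passed the threshold. limma called 0 genes, with 426 at an unadjusted p under 0.05, and also 0 without its trend. With sample weights it called 5 genes, which are Irf9, Cxcl9, Ubd, Cd74 and Plbd1, and among number-only libraries 1 gene, Srp14.

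The MHC class II list had a median log2 fold change of 1.71 with all 8 genes higher, of which 0 passed over all genes and 7 rose adjusted over the list alone (camera adjusted p = 5.07e-13, adjusted p = 0.315 with an estimated correlation). Its score was 3.11 ± 0.87 with anti-PD-1 and 1.64 ± 0.28 with PBS, with no overlap (exact permutation p = 0.00794, adjusted p = 0.107). The T cell score was 0.92 ± 0.22 and 0.56 ± 0.13, also with no overlap (exact permutation p = 0.00794, adjusted p = 0.107). The list's camera adjusted p was 8.63e-08, or adjusted p = 0.518 with an estimated correlation. Interferon-gamma response had a median of 0.85 and 4 of 22 genes risen adjusted over the list alone (camera adjusted p = 5.35e-19, adjusted p = 0.315 with an estimated correlation). That median was 0.47 without vector anti-PD-1 replicate 4 and 1.31 without replicate 1, and 0.64 among M-style against 1.26 among number-only libraries. The MHC class I list had 1 of 20 risen adjusted over the list alone (camera adjusted p = 9.3e-12, adjusted p = 0.315 with an estimated correlation). Skeletal muscle genes were higher as a list by a median of 1.44 with 0 of 19 past the threshold (adjusted p = 0.518 with an estimated correlation). Their median was 0.70 without vector anti-PD-1 replicate 3, and 0.67 among M-style against 2.38 among number-only libraries. DNA repair and cell cycle genes were lower as lists, by medians of -0.20 and -0.20 (adjusted p = 0.71 and 0.752 with an estimated correlation), and lost their calls in 3 and 4 of the 10 fits that left out 1 library. Among those, leaving out vector anti-PD-1 replicate 3 or 5 or vector PBS replicate 3 ended both, and vector PBS replicate 1 ended cell cycle. Camera called 13 lists in all, and fry and the exact score test called 0. Fully separated lists were again too few to pass the exact test after adjustment. The macrophage list had a median of 0.07 and a mean of -0.01, and the p53 and unfolded protein response lists had medians of -0.09 and -0.14 but tested in the higher direction without being called.

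Anti-PD-1 was compared with PBS in mutant tumours, which addresses how these tumours responded to the antibody. T cell and killing genes rose in every member tested. All 17 T cell genes rose, as did all 18 CD8 and cytotoxic genes, and the same numbers rose adjusted over the list alone. Their median log2 fold changes were 2.25 (camera adjusted p = 2.04e-21) and 2.70 (camera adjusted p = 3.62e-16), each with adjusted p = 0.0901 with an estimated correlation. Cd8a went from 1.96 ± 2.97 to 14.9 ± 1.47 FPKM (SD, n = 5), a log2 fold change of 2.97 ± 0.367 (SE, adjusted p = 2.12e-05), and Gzmb from 7.86 ± 10.4 to 76.3 ± 30 FPKM (log2 fold change 3.87, adjusted p = 0.000128). Ifng rose from 1.25 ± 1.81 to 8.02 ± 1.68 FPKM (log2 fold change 2.26, adjusted p = 6.72e-05). The T cell score was 3.29 ± 0.33 with anti-PD-1 and 1.0 ± 0.74 with PBS (exact permutation adjusted p = 0.0179). The list's median was 2.13 among M-style and 2.25 among number-only libraries.

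Brakes on T cells rose with them. Pdcd1, which encodes PD-1 itself, went from 1.82 ± 2.6 to 19.7 ± 4.32 FPKM (log2 fold change 3.3, adjusted p = 8.86e-06), and Cd274, the gene of its ligand PD-L1, from 17.0 ± 10.1 to 72.0 ± 4.71 FPKM (log2 fold change 2.17, adjusted p = 0.00109). In the checkpoint and exhaustion list 12 of 13 genes rose, also adjusted over the list alone, including Cd96, Lag3 and Havcr2. Of the regulatory T cell list 5 of 6 rose, of the NK list 8 of 8, of the B and plasma cell list 6 of 6 and of the dendritic cell list 11 of 13 (5, 8, 6 and 12 adjusted over the list alone). In the macrophage and monocyte list 15 of 20 genes rose, among them Mertk and Ms4a7, and 1 fell, the same as adjusted over the list alone. For each of these 6 lists camera's call was lost with an estimated correlation, at adjusted p = 0.0901. Neutrophil genes rose in 5 of 13 (6 adjusted over the list alone, median 1.20, adjusted p = 0.328 with an estimated correlation), but in 2 of 13 without the 3 libraries least correlated with the rest, where the list was not called (median 0.41, adjusted p = 0.302). Adgre1, the macrophage gene for F4/80, went from 16.1 ± 10.2 to 110 ± 41.1 FPKM (log2 fold change 2.82, adjusted p = 2.07e-05), whereas S100a9 (adjusted p = 0.265) and Arg1 (adjusted p = 0.606) did not pass.

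Antigen presentation and interferon genes rose. The largest rise was that of the T cell chemokine Ccl5, from 5.47 ± 9.08 to 85 ± 39.1 FPKM (log2 fold change 4.59 ± 0.435, adjusted p = 4.82e-06), and H2-Aa rose from 44.1 ± 66.8 to 405 ± 136 FPKM (log2 fold change 4.34, adjusted p = 4.66e-05). H2-Eb1, H2-Ea-ps, H2-Ab1, Gzmf, Ccl8, Cd74, Gzmb and Gzmd were the other genes among the 10 largest rises. All 8 MHC class II genes rose (median 3.46, adjusted p = 0.106 with an estimated correlation), 18 of 20 MHC class I genes (1.26, adjusted p = 0.106), 21 of 22 type I interferon response genes (1.58, adjusted p = 0.106) and 20 of 22 interferon-gamma response genes (1.92, adjusted p = 0.261). Adjusted over the list alone these counts were 8, 18, 21 and 21. In the cGAS and STING list of cytosolic DNA sensing 6 of 9 rose, as adjusted over the list alone (median 0.71, adjusted p = 0.167 with an estimated correlation). Cxcl9 rose from 39.5 ± 41.8 to 171 ± 70.7 FPKM (log2 fold change 2.52, adjusted p = 0.00718).

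**Figure D3:**
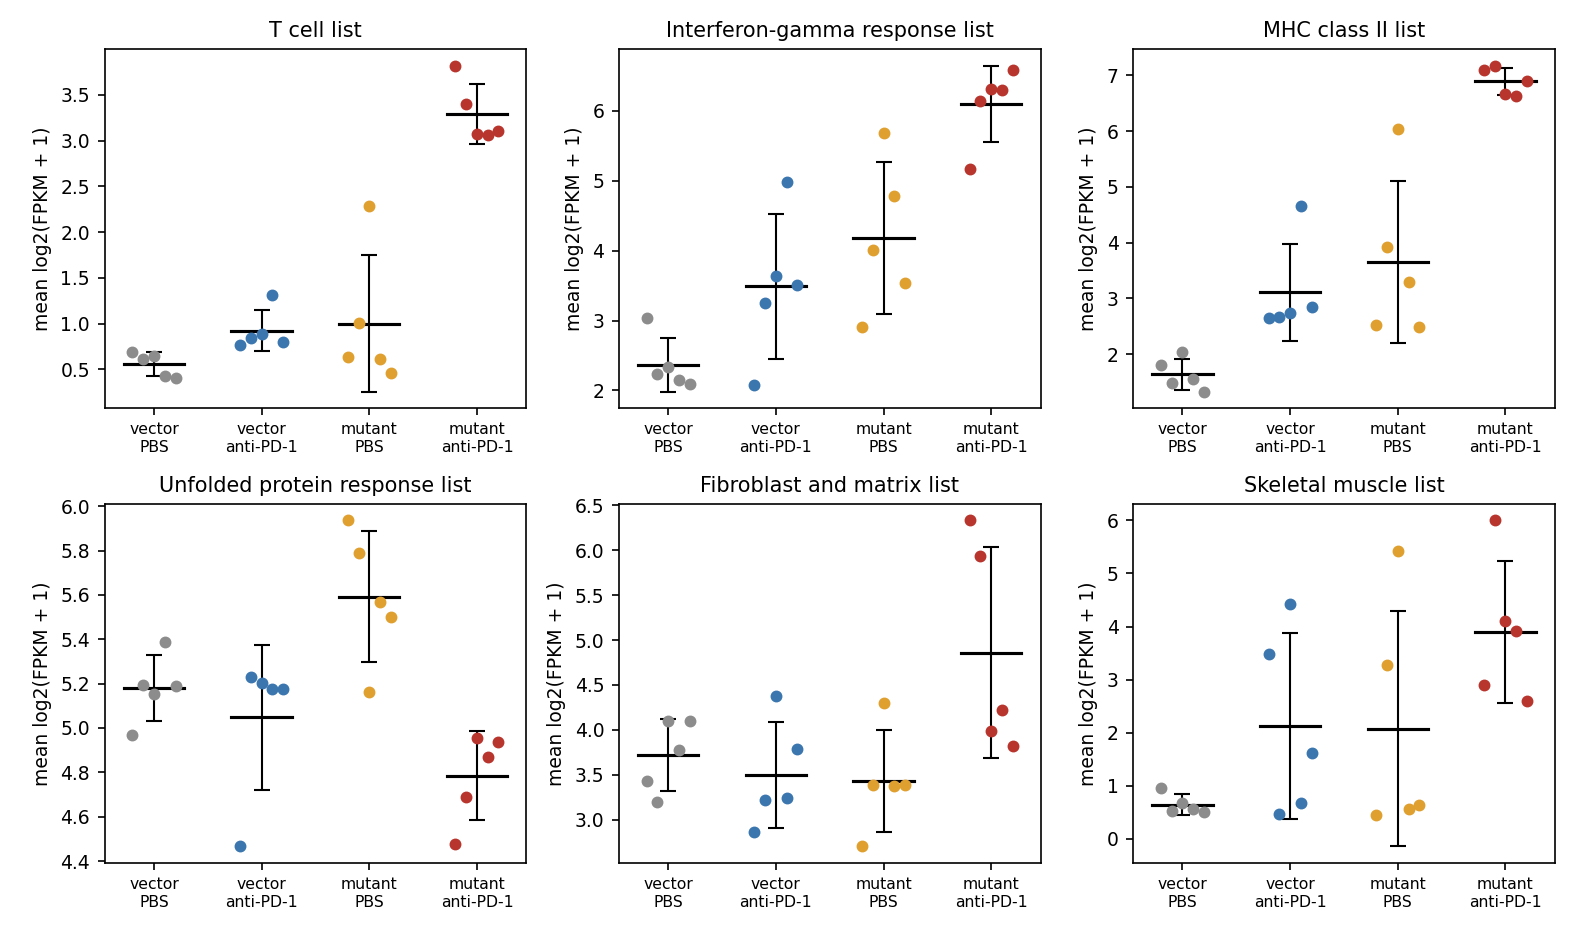
Each point is the score of 1 tumour, the mean log2(FPKM + 1) of a list's genes, the line is the group mean and the bars are the SD of 5 tumours. The T cell score is 3.29 in mutant anti-PD-1 tumours and 1.0 in mutant PBS tumours, with the skeletal muscle score shown in the same way.

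Unfolded protein response genes were lower as a list in the same comparison, and DNA repair and cell cycle genes were so less clearly. Since whole tumours were measured, a lower share of tumour cells was not told apart from lower expression within cells. In the unfolded protein response list, which covers the cell's reaction to misfolded protein, 6 of 14 genes fell and 0 rose, and 10 fell and 1 rose adjusted over the list alone. The median was -0.78 (camera adjusted p = 0.000515, adjusted p = 0.126 with an estimated correlation), and Chac1, Herpud1 and Asns were among the genes that fell. The score was 4.79 ± 0.20 with anti-PD-1 and 5.59 ± 0.30 with PBS, with no overlap (exact permutation adjusted p = 0.0179). Mutant PBS replicate 3 had the lowest score of the mutant PBS tumours, at 5.16, and without it the list's median was -0.925. DNA repair genes fell in 16 of 35 cases (19 adjusted over the list alone, median -0.47, adjusted p = 0.375 with an estimated correlation), including Ercc1 and Xrcc5. Cell cycle genes fell in 9 of 29 (14 adjusted over the list alone, median -0.48, adjusted p = 0.421 with an estimated correlation), including Pcna and Mcm7, while Mki67 did not pass (adjusted p = 0.0882). Cell cycle had a median of -0.89 among M-style and -0.14 among number-only libraries. Without the 3 libraries least correlated with the rest its median was -0.07 and it was not called (adjusted p = 0.319), and that of DNA repair was -0.17. The cell cycle scores of mutant anti-PD-1 replicates 1 and 2 were 3.31 and 4.16, and those of the other 3 were 4.60 to 5.00. Replicates 1 and 2 are the only M-style tumours of that group, so the split by style and the fit without the 3 libraries are not separate checks. Neither list's score passed the exact permutation test (adjusted p = 0.277 for cell cycle and 0.139 for DNA repair). Of p53 targets 5 rose and 10 fell of 21 (6 and 10 adjusted over the list alone), and the list was not called (adjusted p = 0.224). Fas rose by a log2 fold change of 0.997, and Cdkn1a fell from 76.6 ± 16.8 to 46.8 ± 9.77 FPKM (log2 fold change -0.80, adjusted p = 0.0164), a call lost without the style term or with the muscle term (adjusted p up to 0.0927).

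The largest fall was that of Car6, the gene of a secreted carbonic anhydrase, which went from 30.3 ± 19.2 to 0.998 ± 0.49 FPKM (log2 fold change -3.63, adjusted p = 1.87e-05), and Areg, a ligand of the EGF receptor, from 24.7 ± 12.1 to 2.32 ± 1.42 FPKM (log2 fold change -2.96, adjusted p = 1.41e-05). Mutant PBS replicate 3, with the highest T cell score of its group (2.28), was already low without antibody. It had 4.81 FPKM of Car6 and 7.08 of Areg, against 22.8 or more of each gene in the rest of its group. The mutant anti-PD-1 tumours were lower still, at up to 1.62 FPKM of Car6 and 4.51 of Areg. Whether these falls follow the antibody itself or the immune cells present was not tested. Cdsn, Angptl6, Ereg, Soat2, AL805899.1, Avil, P2rx3 and Trib3 were the other genes among the 10 largest falls, and AL805899.1 was not called without the 3 libraries (adjusted p = 0.233). In all 4271 genes differed, 2226 higher and 2045 lower, of which 1288 rose and 249 fell at least 2-fold. Median centring, which moved the median of all genes from -0.10 to -0.13, gave 2268 higher and 2705 lower, or 45.6% against 52.1% higher, and sample weights gave 2942 and 3518. M-style libraries alone gave 3126 genes and number-only libraries 4317. Without mutant anti-PD-1 replicate 1 the count was 2754.

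Stromal genes rose as well. In the fibroblast and matrix list 16 of 21 genes rose, including Fbln1, Fap and Col1a1 (18 adjusted over the list alone, median 1.48, adjusted p = 0.311 with an estimated correlation), and in the endothelial list 12 of 14 (12 adjusted over the list alone, median 1.0, adjusted p = 0.261 with an estimated correlation). The fibroblast median was 2.86 among M-style and 0.54 among number-only libraries. Mutant anti-PD-1 replicates 1 and 2, the only M-style tumours of that group, had fibroblast scores of 6.33 and 5.94. The other 3 had 3.83 to 4.22. The split by style and the fit that follows are thus not separate checks. Without the 3 libraries least correlated with the rest, 0 fibroblast genes and 1 endothelial gene rose past the threshold, while 17 T cell genes still did, and the fibroblast, TGF-beta and adipocyte lists were not called. With the muscle score as a term, 9 interferon-gamma, 17 T cell and 2 fibroblast genes rose, while the medians of these lists were 1.72, 2.01 and 1.08, and camera still called all 3. TGF-beta response genes rose in 6 of 14 and fell in 1 (7 and 1 adjusted over the list alone, adjusted p = 0.394 with an estimated correlation). Adipocyte genes rose in 3 of 9 (4 adjusted over the list alone, adjusted p = 0.311) and skeletal muscle genes in 2 of 19 (0 adjusted over the list alone, median 2.24, adjusted p = 0.441). Camera called 22 lists, and the hypoxia, keratin, erythroid, p53 and immediate early lists were not called, the last with a median of -0.19 and a mean of 0.07. The keratin score was 1.08 ± 0.25 with anti-PD-1 and 1.49 ± 0.17 with PBS (exact permutation adjusted p = 0.0402).

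The interaction, which is the anti-PD-1 response in mutant tumours minus that in vector tumours, addresses whether the tumour types responded differently to the antibody. On the log2(FPKM + 1) scale, T cell, cytotoxic and macrophage genes rose more in mutant than in vector tumours. In all 17 T cell genes the response was larger in mutant tumours (17 adjusted over the list alone, median difference 1.99, camera adjusted p = 1.76e-19, adjusted p = 0.146 with an estimated correlation). It was larger in 15 of 18 CD8 and cytotoxic genes (median 2.17), 13 of 20 macrophage genes (16 adjusted over the list alone, median 1.72) and 14 of 22 type I interferon genes (18 adjusted over the list alone, median 1.59, adjusted p = 0.206 with an estimated correlation). With an estimated correlation camera called 0 lists in the interaction, and fry called 14. Without the 3 libraries the counts of these 4 lists were 13, 8, 3 and 2, and the medians 1.84, 2.40, 1.26 and 1.48. Ccl5 differed by a log2 value of 4.04 (adjusted p = 0.00236), Pdcd1 by 2.81 ± 0.494 (SE, n = 5 per group, adjusted p = 0.00378), Cd8a by 2.40 (adjusted p = 0.00899) and Adgre1 by 3.02 (adjusted p = 0.0029). Ifng differed by 1.75 (adjusted p = 0.0243), a call lost without mutant PBS replicate 2 or 5 or mutant anti-PD-1 replicate 2 (adjusted p up to 0.0548) and without the 3 libraries least correlated with the rest (adjusted p = 0.0596). In vector tumours Cd8a went from 0.043 to 0.620 FPKM and Ifng from 0.006 to 0.500, all below the pseudocount of 1. In mutant tumours Cd8a went from 1.96 to 14.9 and Ifng from 1.25 to 8.02. Adding 1 flattens changes at such low levels, so the differences for Cd8a and Ifng depend on it. Adgre1 lay well above it in vector tumours, at 15.1 and 13.5 FPKM. With a pseudocount of 0.1 the interaction had 876 genes, 699 positive and 177 negative.

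The interferon-gamma response list was also higher in the interaction, but no single gene of it passed, over all genes or adjusted over the list alone. Its median difference was 0.86 (camera adjusted p = 0.0268, adjusted p = 0.668 with an estimated correlation). Leaving out 1 library ended that call in 6 of 20 fits, namely vector PBS replicate 1, vector anti-PD-1 replicates 2 and 5, mutant PBS replicates 1 and 5, and mutant anti-PD-1 replicate 5, and among M-style libraries the median was 0.45 (adjusted p = 0.356). Cxcl9 differed by -0.09 (adjusted p = 0.967). In the MHC class II list 1 of 8 genes passed over all genes, the regulator Ciita, and 7 adjusted over the list alone (median 1.97, camera adjusted p = 0.000269, adjusted p = 0.329 with an estimated correlation), and H2-Aa did not pass (adjusted p = 0.0793). Among M-style libraries that list was not called (median 1.43, adjusted p = 0.103). No fibroblast gene passed over all genes, and 17 of 21 did adjusted over the list alone (median 1.58, adjusted p = 0.336 with an estimated correlation). That median was 3.25 among M-style and 0.40 among number-only libraries, and 0.47 without the 3 libraries, which are all M-style, so these are not separate checks.

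The unfolded protein response list fell more in mutant than in vector tumours, with 4 of 14 genes past the threshold (7 adjusted over the list alone, median -0.51, camera adjusted p = 0.000301, adjusted p = 0.146 with an estimated correlation). That count was 1 without the 3 libraries and 2 with the muscle term, with medians of -0.60 and -0.48. Under PBS its score was 5.59 ± 0.30 in mutant and 5.18 ± 0.15 in vector tumours (exact permutation adjusted p = 0.134). Under anti-PD-1 the scores were 4.79 ± 0.20 and 5.05 ± 0.33 (exact permutation adjusted p = 0.195). Car6 differed by -3.57 (adjusted p = 0.00378) and Trib3 by -2.07 (adjusted p = 0.00581), the latter lost without the 3 libraries (adjusted p = 0.0516). The largest positive difference was that of Gzmf, at 4.36 (adjusted p = 0.0291), and Gzmd and Gzme also had positive differences. The mean of Gzmf was lowest in mutant PBS tumours, although vector anti-PD-1 replicate 3 (0.89 FPKM) lay within their range of 0.206 to 1.73, and each of these 3 calls was lost without vector PBS replicate 1, 2 or 5, vector anti-PD-1 replicate 2, mutant PBS replicate 1 or 2, or mutant anti-PD-1 replicate 1 (adjusted p up to 0.0757), and also without the style term or without the 3 libraries (up to 0.0988). Interaction calls numbered 1308 genes, 1035 with a positive and 273 with a negative difference, and 902 were at least 2-fold. Median centring, which moved the median of all genes from 0.01 to -0.11, gave 962 positive and 452 negative calls, or 68% against 79.1% positive. Sample weights gave 1719 positive and 1495 negative calls (53.5% positive). The count was 2247 without vector anti-PD-1 replicate 1, with 1253 positive and 994 negative, and 387 without the 3 libraries least correlated with the rest. It was 849, 797 and 814 without vector PBS replicates 3, 4 and 5, 745, 760 and 816 without mutant PBS replicates 1, 2 and 5, and 782 and 688 without mutant anti-PD-1 replicates 1 and 2. Each style alone gave 1156 (M-style) and 1164 (number-only) genes, and camera called 21 lists.

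**Figure D4:**
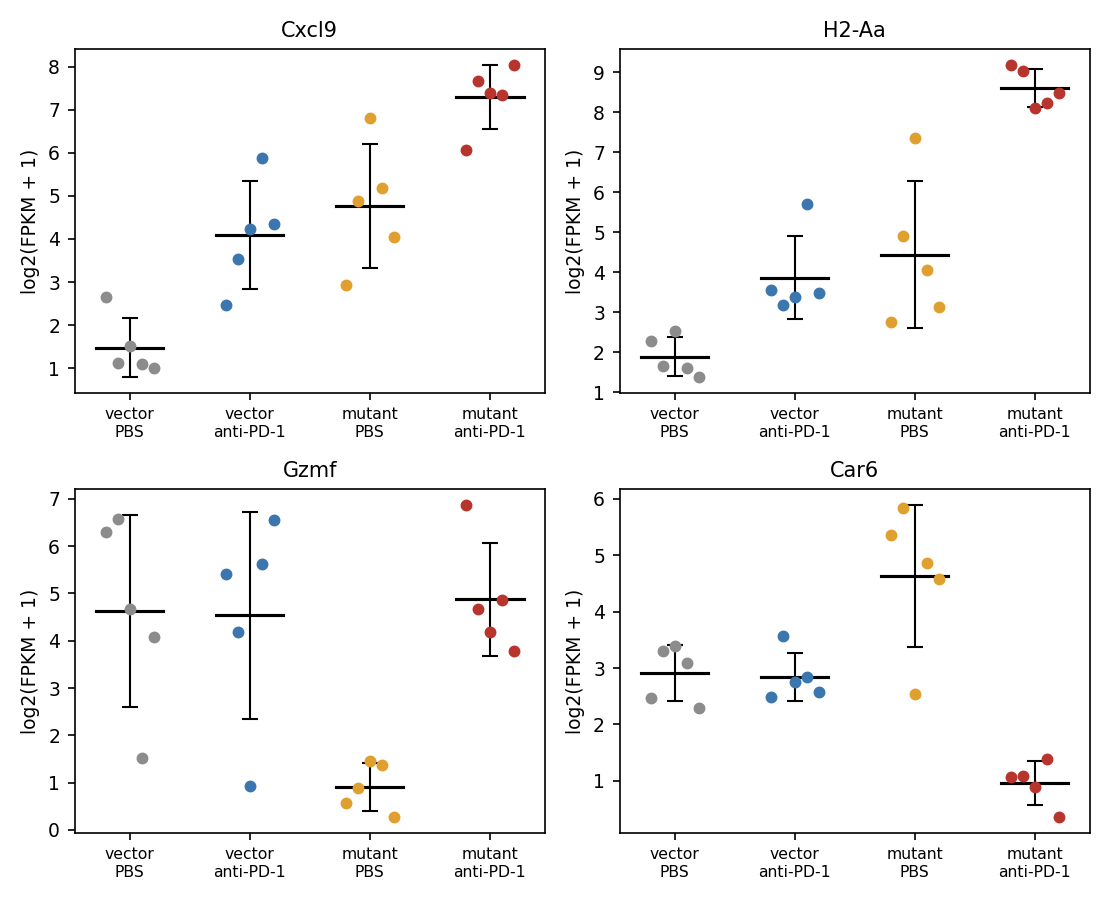
Each point is the log2(FPKM + 1) of Cxcl9, H2-Aa, Gzmf or Car6 in 1 tumour, the line is the group mean and the bars are the SD of 5 tumours. Mean Gzmf is 0.975 FPKM in mutant PBS tumours and 39.8 FPKM in mutant anti-PD-1 tumours, and mean Car6 is 30.3 and 0.998 FPKM.

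Mutant and vector tumours were also compared under anti-PD-1, which addresses how the treated tumours differed. T cell, class II and interferon-gamma genes were higher in the mutant tumours. H2-Ea-ps and H2-Eb1 had the largest rises, and H2-Aa rose from 17.9 ± 18.6 FPKM in vector to 405 ± 136 in mutant tumours (SD, n = 5), a log2 fold change of 4.92 ± 0.597 (SE, adjusted p = 1.43e-05). Ccl5 rose by 4.33 (adjusted p = 3.57e-06), Serping1 by 4.13 (adjusted p = 4.4e-06) and the cytotoxic granule gene Nkg7 by 4.03 (adjusted p = 4.55e-06). All 17 T cell genes rose (17 adjusted over the list alone, median 2.24, camera adjusted p = 5.59e-19, adjusted p = 0.145 with an estimated correlation), 8 of 8 MHC class II genes (median 4.07, adjusted p = 0.145) and 21 of 22 interferon-gamma genes (22 adjusted over the list alone, median 2.76, adjusted p = 0.22). Cldn6, a tight junction gene of embryonic epithelia, fell from 30.3 ± 11.8 to 3.67 ± 2.77 FPKM (log2 fold change -3.01, adjusted p = 8.54e-06), and Plet1, C78283, Oplah, Zfp985, Glod5 and Ankrd1 fell too. Cell cycle genes fell in 9 of 29 (13 adjusted over the list alone, median -0.51, adjusted p = 0.388 with an estimated correlation), with a median of -0.13 among number-only libraries. Fibroblast genes rose in 15 of 21 (18 adjusted over the list alone, median 1.23, adjusted p = 0.375), with a median of -0.05 among number-only libraries. Without the 3 libraries neither list was called, with medians of -0.16 for cell cycle (adjusted p = 0.0618) and 0.12 for fibroblast genes (adjusted p = 0.301). Those libraries are all M-style, so this fit and the number-only medians are not separate checks. Over all tumours neither score passed the exact permutation test (adjusted p = 0.27 for cell cycle and 0.0677 for fibroblast genes). In all 4601 genes differed, 2489 higher and 2112 lower. Median centring, which moved the median of all genes from 0.002 to -0.13, gave 2248 higher and 3291 lower, or 40.6% against 54.1% higher. M-style libraries alone gave 3912 genes and number-only libraries 3208.

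Averaged over the treatments, mutant tumours differed from vector tumours in 3455 genes, 1906 higher and 1549 lower, or 1751 and 2140 after median centring (45.0% against 55.2% higher). All 22 interferon-gamma genes rose (median 2.32, camera adjusted p = 2.37e-16, adjusted p = 0.185 with an estimated correlation) and all 8 MHC class II genes (median 3.23, adjusted p = 0.185), while C78283 had the largest fall (log2 fold change -2.70). Averaged over the tumour types, anti-PD-1 changed 2604 genes, 1426 higher and 1178 lower, or 4260, 2094 higher and 2166 lower, without vector anti-PD-1 replicate 1. All 17 T cell genes rose (median 1.22, camera adjusted p = 2.91e-24, adjusted p = 0.0703 with an estimated correlation), and the muscle actin gene Acta1 had the largest rise (3.3, adjusted p = 0.0348), which was lost without vector PBS replicate 2, 3 or 4, vector anti-PD-1 replicate 3 or 5, mutant PBS replicate 1, 4 or 5, or mutant anti-PD-1 replicate 2 or 4 (adjusted p up to 0.0718), and also without the 3 libraries or with the muscle term (up to 0.276).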

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

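The splits for the interaction and the tests of the tumour cell share, of muscle and of the 2 libraries that stand apart were chosen after the result was seen.

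The response to anti-PD-1 differed between mutant and vector tumours in 1308 genes and 21 gene lists by limma's interaction and camera. Exchanging genotype within treatment also breaks the mean genotype difference, so that difference was first taken out of the values. Of 100 such splits 2, the real one among them, gave 1308 or more genes, and the highest other gave 1578. Without that step the highest other gave 4, a count that does not test the interaction alone. Chance rarely gave that count but is not excluded, since another split gave more genes than the real one. Which samples that split exchanged was not examined. With an estimated correlation camera called 0 of the lists, and fry called 14 of the 27 tested.

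Immune and stromal markers rose together in mutant tumours under anti-PD-1. A lower share of tumour cells alone would raise all other cells alike, but the T cell score rose more than the endothelial score by 1.38 (exact permutation p = 0.0159, n = 5). Muscle taken with the tumour was argued against as the whole cause, since 17 of 17 T cell genes rose with the muscle score as a term, with a median log2 fold change of 2.01 against 2.25 without that term. Interferon-gamma response genes past the threshold went from 20 to 9, but their median only from 1.92 to 1.72, with a median SE of 0.528 and then 0.591. These genes lay close to the threshold (median adjusted p = 0.0132) and had a somewhat smaller fold and a larger SE with the term. Fewer genes passed in all, 2622 against 4271, which also makes the adjustment stricter. The lost calls therefore do not point to muscle as the cause of that rise. Without vector anti-PD-1 replicate 1 and mutant anti-PD-1 replicates 1 and 2, 17 of 17 T cell genes rose but 0 of 21 fibroblast genes did (median log2 fold change 0.38 against 1.48, median SE 0.343 against 0.45), so the rise of fibroblast genes may rest on 2 mutant libraries. Those 2 are the only M-style libraries of mutant anti-PD-1, so single tumours cannot be told apart there from what the identifier style marks. More immune cells or stronger activity in each, in response to the antibody and the mutant that the design names, stay open and were not tested.

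A single tumour lay far from the other 4 of its group, by the gap to its nearest neighbour relative to the range of the group, in 29 of 208 groups over 52 measures. Chance alone marks about 1 in 20 groups, and the measures overlap. Gene values are in FPKM and were tested on the log scale.

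Mutant PBS replicate 3 was marked 10 times. Its scores were 2.53 for checkpoint genes, 1.91 for regulatory T cells, 2.14 for dendritic cells, 3.99 for cGAS and STING genes and 2.52 for endothelial genes. It had 13560 genes at 1 FPKM or more against 12474 to 12735 in the others, Cd4 at 1.13, Foxp3 at 0.533 and H2-K1 at 203 FPKM, and Cdkn1a at 48 FPKM against 75.8 to 88.8. Its skeletal muscle score of 5.42 was the highest in the group.

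Vector anti-PD-1 replicate 1 was marked 7 times, with a total of 566913 FPKM, 8.40% from small RNA genes, a mean Spearman correlation of 0.873, scores of 2.94 for p53 targets, 2.20 for TGF-beta response and 4.47 for the unfolded protein response, and Cdkn1a at 17 FPKM against 45.1 to 61.3. Vector anti-PD-1 replicate 4 had a T cell score of 1.31 against 0.766 to 0.883, an MHC class II score of 4.66 and H2-Aa at 51.2 FPKM against 8.0 to 10.9. Mutant anti-PD-1 replicate 1 had a CD8 and cytotoxic score of 4.79, Gzmb at 130 FPKM against 57.4 to 65.6, and Ifng at 5.10 FPKM against 8.23 to 9.17.

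Among vector PBS tumours, replicate 1 had scores of 3.03 for interferon-gamma and 4.01 for type I interferon response, replicate 2 a cell cycle score of 4.88, and replicate 3 an adipocyte score of 1.07 and Cd8a at 0.128 FPKM. Replicate 5 had Ifng at 0.03 FPKM, near the floor. No biological explanation was tested for the single tumours.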

How the results depend on the processing

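The fits without the 3 libraries least correlated with the rest, with the skeletal muscle score as a term and with sample quality weights were tests chosen after the data were seen. No paired analysis was possible because the labels give no shared replicate numbers. Alternatives for read counts were not run because the files hold FPKM, and the depth, which limits precision at low levels, is unknown.

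Over the alternatives run for them, named genes gave 4408 values with the same direction and side of the threshold, 33 newly past it, 207 no longer past it and 0 reversed. Gene lists gave 3827, 101 and 272 in the same order and 5 reversed. Pole stayed past the threshold in 14 of 14 alternatives under anti-PD-1 (adjusted p = 3.71e-05 to 0.0152) and in 24 of 24 averaged over the treatments, and passed in 2 of 14 under PBS. The cause was not tested for any change below except where the construction gives it.

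Fewer genes were tested with a filter of 5 FPKM, which gave 2742 genes for the mutant response, 98 for mutant against vector under PBS, 2993 under anti-PD-1, 663 for the interaction, 2165 for the mean genotype and 1610 for the mean treatment difference. A 2-fold minimum, a stricter rule, gave 1537, 84, 1740, 551 and 414 for the same results without the interaction. Without the style term the mean treatment difference had 1716 genes. With only the compared groups, mutant against vector had 924 genes under PBS and 2343 under anti-PD-1. M-style libraries gave 12 under PBS and 1593 for the mean treatment difference, and number-only libraries 1 for the vector response.

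Camera with an estimated correlation called 0 lists in each of the 7 comparisons, and fry called 0 for the vector response and 0 for mutant against vector under PBS. In the other comparisons fry called 22 lists for the mutant response, 21 for mutant against vector under anti-PD-1 and 14 for the interaction. It called 18 for the mean genotype and 18 for the mean treatment difference. Without the 3 libraries, 1643 genes differed between mutant and vector under PBS, a comparison that holds none of them, and among these were all 203. The spread shared by all groups is estimated without them there. The interaction had 387 genes. The muscle term left 8 lists for the vector response, and 2622 genes for the mutant response, 1942 for the mean genotype and 611 for the mean treatment difference. Sample weights gave 5 genes for the vector response, 6460 for the mutant response, 2710 for mutant against vector under PBS, 3214 for the interaction, 5451 for the mean genotype and 4836 for the mean treatment difference.

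Leaving out 1 library gave 0 to 0 genes for the vector response, 2754 (mutant anti-PD-1 replicate 1) to 4354 for the mutant response, 83 (vector PBS replicate 1) to 215 for mutant against vector under PBS, 3280 to 6042 under anti-PD-1, 688 (mutant anti-PD-1 replicate 2) to 2247 (vector anti-PD-1 replicate 1) for the interaction, 2629 to 4991 for the mean genotype and 1808 to 4260 (vector anti-PD-1 replicate 1) for the mean treatment difference. Lists called ranged from 9 to 16, 22 to 22, 10 to 15, 20 to 23, 19 to 22, 21 to 22 and 21 to 22 in the same order.

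The reversed lists were immediate early genes under PBS in number-only libraries (median -0.245), fibroblast genes in number-only libraries under anti-PD-1 (-0.051) and for the mean genotype (-0.251), fibroblast genes for the mean genotype without the 3 libraries (-0.028), and cell cycle genes for the interaction without them (0.064). Single-gene calls lost in several fits include Snord100 for the interaction, in 15 of 20 without 1 library. For the mutant response Pole was lost without mutant PBS replicate 1, 2, 3 or 4 or mutant anti-PD-1 replicate 1 or 4 (adjusted p up to 0.18, and up to 0.234 over all 14 alternatives), and Chek2 without mutant PBS replicate 2, 3 or 5 or mutant anti-PD-1 replicate 1 or 4 (up to 0.119, and 0.223 over all).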

Other observations

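Genes in these paragraphs and the tests of the Pole region and of chromosome 1, except that of host cells, were chosen after values were seen.

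Some growth factor and amino acid genes fell in mutant tumours under anti-PD-1, and no list of either was fixed or tested. The values are of whole tumours, so a lower share of tumour cells was not told apart from lower expression within cells. Among ligands of the EGF receptor, which drive epithelial growth, Areg fell, Hbegf went from 55.1 to 15.8 FPKM (log2 fold change -2.12, adjusted p = 0.000685), Ereg from 109 to 28.4 (-2.33, adjusted p = 0.00274), Btc from 17.1 to 6.54 (-1.86, adjusted p = 0.00713) and Tgfa from 1.45 to 0.838 (-0.54, adjusted p = 0.0128). The response differed from that in vector tumours for Areg (interaction adjusted p = 0.00378) and Hbegf (0.0484) and not past the threshold for Ereg (0.126), Btc (0.26) and Tgfa (0.155). Some genes tied to amino acid supply also fell. Atf5 went from 235 to 97.4 FPKM (-1.51, adjusted p = 0.00015), Asns from 114 to 43.4, the serine and folate enzymes Shmt2 from 76.3 to 35.9 and Mthfd2 from 60 to 24.5, and the glutamine carrier Slc1a5 from 56.5 to 25.5 (-1.13, adjusted p = 5.08e-05).

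Some genes separated the tumour types whatever the treatment. Masp1, a complement protease gene, averaged 3.99 FPKM in vector PBS and 0.581 in mutant PBS tumours (log2 fold change -1.66, adjusted p = 6.85e-05), and Wasf1, an actin regulator, 1.36 and 0.621. Masp1, Wasf1, Tmem121, Gm773, Zfp988 and Gm32857 were under 1 FPKM in every mutant library and at or above it in every vector library, and Prkd1, a kinase gene, was the other way round (0.537 and 1.38). Several zinc finger genes of a cluster on chromosome 4 were lower in mutant PBS tumours, among them Zfp978 (4.34 to 1.02 FPKM) and Zfp982 (2.43 to 0.301), and their reads can be shared. Zfp991 was 4.86 in vector PBS, 1.53 in mutant PBS and 6.74 in mutant anti-PD-1 tumours. H2-Ea-ps is a pseudogene in the reference strain, while BALB/c mice carry a working copy.

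Pole was lower in mutant than in vector tumours. Loss or silencing of its chromosome region is argued against, since the 27 tested genes within 1 Mb had a median log2 fold change of 0.027 (interval from resampling the genes -0.092 to 0.088). Fewer dividing cells is argued against as the whole cause, since with the cell cycle score as a term Pole was still lower by -0.492 (interval -0.689 to -0.294, adjusted p = 0.00259), having been -0.776 without it. A change at the gene itself in the mutant cells may remain, as a hypothesis, and clonal selection and editing at the gene stay open and were not tested.

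Genes of chromosome 1 were lower in mutant than in vector tumours under PBS, with a median of -0.211 over 571 genes. The medians and shares by chromosome cover genes with a mean log2(FPKM + 1) of at least 2. Among all tested genes, 27 of the 129 fallen ones lay on chromosome 1. A shift of all genes by scaling is argued against by the medians of the other 18 autosomes (-0.119 to 0.119), and a few strongly changed genes by the 79.2% of chromosome 1 genes that were lower (interval 75.6 to 82.4, against 47.2% elsewhere together, where chromosome 19 came closest at 73.5% with a median of -0.119). More host cells in mutant tumours would put the median further below 0 under anti-PD-1, where immune genes rose. It was -0.195 there, a difference of 0.016 (interval -0.032 to 0.059). Both of these intervals treat genes as independent and leave out the spread between tumours. By the mean of the tumours, mutant differed from vector by -0.218 under PBS and -0.142 under anti-PD-1, also not further below 0. A lower copy number in the mutant cell line may explain it, as all 10 windows of 20 Mb were below 0, and this stays a hypothesis without DNA data. Per tumour the value was -0.222 ± 0.009 in mutant PBS and -0.004 ± 0.024 in vector PBS tumours (SD, n = 5, exact permutation p = 0.00794), and under anti-PD-1 -0.181 ± 0.05 and -0.039 ± 0.116 (exact permutation p = 0.0476), with vector anti-PD-1 replicate 1 at -0.244.

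The same samples were split into groups of the same sizes, with 100 splits, the real one included, for each comparison except the interaction. These splits show how often other groupings gave as many genes. For the mutant response 1 split gave 4271 or more genes and the highest other gave 2353, for mutant against vector under PBS 1 gave 203 or more and the highest other gave 5, and under anti-PD-1 1 gave 4601 or more and the highest other gave 1315. For the mean genotype difference 1 gave 3455 or more and the highest other gave 776, and for the mean treatment difference 2 gave 2604 or more, the highest other with 2643. For the first 4 counts no other drawn split gave as many genes, so chance is unlikely. Chance is not excluded for the mean treatment difference, where 1 other split gave more genes than the real one. For the vector response the real count was 0, so all 100 splits give as many by construction and nothing follows from them, and the highest other gave 2. Why other splits gave up to 2353, 1315, 776 and 2643 genes, the last more than the real split, was not examined.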
